A study of Mus musculus with 26 samples.

How the data were processed

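Lung RNA was measured on 26 Affymetrix expression arrays, each hybridised with RNA pooled from 3 animals, so the spread between arrays is a spread between pools and not between single animals. Per the labels the arrays fall into 9 groups: wild type (WT), compound heterozygous (DHet) and double mutant (DKO) for Fgfr3 and Fgfr4, each in 3 age sets. A group holds 3 arrays, except the WT of the 28-day set, which holds 2. In 18 samples the title and the source name give an age of 8 or 1 day while the description and characteristics give the opposite. These samples were grouped by title, the 2 sets are called the set titled 8 day and the set titled 1 day, and no order in age was read between them. The titles call the arrays biological replicates and the pools were taken as separate. The wild types are described as age-matched C57BL6 mice, and the strain background of the mutants was not given in the sources used here.

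The values used are the log2 probe set levels deposited by the authors, which run from 2.68 to 14.8 in a table of 45101 probe sets. The summarisation and normalization methods were not given in the sources used here. Arrays of a set share nearly one distribution (mean range of the sorted values between arrays 0.0791, 0.0372 and 0.102 log2 in the 28-day set, the set titled 8 day and the set titled 1 day, against 1.17 over all arrays). The medians of the array medians were 5.87, 5.30 and 6.71, so the sets look normalized separately by the authors. Comparisons between sets are therefore given relative to the median difference of all probe sets.

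The 64 control probe sets were left out. Of the other 45037, 34945 name 1 gene, 932 name several and 9160 have no gene name in the annotation used. Symbols were matched through Entrez identifiers for 34741 probe sets and kept as given for 204, which gives 18193 genes. Probe sets with a mean over all arrays in the upper 60% were kept (mean of at least 5.38 log2), leaving 27022 probe sets and 13079 genes. Where on the transcripts the probes lie, and which part of each receptor gene was deleted, was not given in the sources used here.

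All 26 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, no covariates, 17 residual degrees of freedom and 4.89 prior degrees of freedom). Genotypes were compared within each set, as the mean over the 3 sets for DKO against WT and DKO against DHet, and the WT of the sets were compared with each other. A moderated F test asked whether the difference between DKO and WT differed among the sets. P values were adjusted by the method of Benjamini and Hochberg over the 27022 probe sets within a comparison, and a probe set was called at an adjusted p under 0.05. Errors of a difference are standard errors (SE) of the fit, and errors of a group mean are standard deviations (SD) between arrays. The fit shares 1 spread per probe set over the 9 groups, so a p does not measure a spread particular to 1 group. The number of arrays limits the precision.

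Before the data were examined, 33 gene lists were fixed for lung cell types, matrix and signalling pathways, tissues that can be dissected along with lung, and technical signals. Of their 632 members 513 had a kept probe set (81.2%), and a gene was represented by its probe set with the highest mean. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists within a comparison, and again with an estimated correlation. Member counts are of members called over all probe sets unless given as adjusted over the list alone, and in comparisons between sets of members above or below the median difference, without a test. A list's shift is the median log2 difference of its members minus the median over all genes.

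The genes to be named were fixed by rule at the same time. They are (a) Fgfr3 and Fgfr4 with all their probe sets, Eln and Igf1 in each genotype comparison, where values are given only for probe sets above the level filter. They are (b) the 6 largest rises and the 6 largest falls in each comparison of DKO with WT or DHet within a set, among probe sets that name 1 gene, are called and have arrays that do not overlap between the groups, with 1 probe set per gene, that with the smallest p. For (c) the other comparisons the same rule takes 4 and 4, where a comparison averaged over sets needs the same direction in all 3 sets instead of no overlap, and the F test gives the 8 smallest adjusted p. They are also (d) up to 4 members per list with the smallest adjusted p, and (e) genes that a test in the closing section is about. Since the smallest p picks the probe set, a printed fold can exceed that of the other probe sets of the gene. Of the 101 genes named for their size in the comparisons of genotypes, 48 have another kept probe set, at least 1 of which was not called for 29 and had the opposite sign for 5.

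The pipeline was tested on simulated data, in which 67, 67 and 66 of 27022 probe sets were changed by 0.5, 1 and 2 log2. Over the 9 comparisons of genotypes within sets the share called ran from 29.9% to 67.2% at 0.5 log2, from 92.5% to 100.0% at 1 log2 and from 98.5% to 100.0% at 2 log2, with 3 to 15 false calls. When the members of 1 list were shifted by 0.4 log2, that list had an adjusted p of 1.38e-22 and limma's camera called 0 of the 32 other lists. The simulated noise was independent between genes and arrays and had the same spread in every group. On the real arrays the median SD ran from 0.0866 to 0.1356 log2 between groups, and genes of a list can be correlated. The simulated rates therefore do not give the rate of false calls on the real arrays.

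Alternatives were an offset of 16 added on the linear scale, no level filter, the upper 40% of probe sets, quantile normalization, eBayes with trend and robust options, array weights, the replicate number as a block, a fit on the groups compared alone, a minimum fold of 1.5 and leaving out each array in turn. For lists they also included the median over all probe sets of a gene. A covariate for the level of the Y-linked gene Eif2s3y, and array medians subtracted in the comparisons between sets, were added after seeing the data. Splits of the arrays into groups of the same sizes were counted, with the real split among them. These were all 10 for 3 arrays against 3. For results over several sets they were 100, drawn at random within sets apart from the real one.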

Results

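Gene expression was measured in lung of mice with mutations of the fibroblast growth factor receptors Fgfr3 and Fgfr4. The 28-day set held 2 WT, 3 DHet and 3 DKO arrays, and the sets titled 8 day and 1 day held 3 arrays of each genotype. Array medians were between 5.84 and 5.89 log2 in the 28-day set, between 5.28 and 5.32 in the set titled 8 day and between 6.68 and 6.74 in the set titled 1 day. Within a set, arrays correlated across probe sets with r of at least 0.985.

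The first question was whether the targeted receptors differed between the genotypes. Fgfr3 was lower in DKO than in WT lung in all 3 sets. In the 28-day set its level was 9.04 ± 0.0345 log2 (SD, n = 3) in DKO and 10.11 ± 0.23 (SD, n = 2) in WT, which is 2.10-fold lower (log2 -1.07 ± 0.147 SE, adjusted p = 0.000251). It was 1.83-fold lower in the set titled 8 day (log2 -0.87 ± 0.131, adjusted p = 0.000512) and 2.47-fold lower in the set titled 1 day (log2 -1.31 ± 0.131, adjusted p = 3.79e-05). A second Fgfr3 probe set fell in the same comparisons, by log2 -0.83 (adjusted p = 0.0102), -0.77 (adjusted p = 0.00578) and -1.28 (adjusted p = 0.000394). DHet lung was between the other groups, with Fgfr3 at log2 -0.49 (adjusted p = 0.612), -0.40 (adjusted p = 0.421) and -0.48 (adjusted p = 0.0362) relative to WT. In the second probe set these differences were -0.07 (adjusted p = 0.999), -0.24 (adjusted p = 0.798) and -0.53 (adjusted p = 0.0476). DKO was lower than DHet in Fgfr3 by log2 -0.58 (adjusted p = 0.0137) in the 28-day set and by -0.82 (adjusted p = 0.0232) in the set titled 1 day, with -0.47 (adjusted p = 0.0773) in the set titled 8 day. The second probe set was lower at 28 days (-0.76, adjusted p = 0.00545) and not called in the sets titled 8 day (-0.53, adjusted p = 0.094) and 1 day (-0.75, adjusted p = 0.0986). Fgfr4 fell in DKO only in the set titled 8 day among the 3 sets (1.93-fold lower than WT, log2 -0.95 ± 0.114, 7.01 ± 0.286 SD against 7.96 ± 0.141 SD, n = 3 each, adjusted p = 3.77e-05). In the 28-day set it differed by log2 0.02 (adjusted p = 0.978) and in the set titled 1 day by -0.21 (adjusted p = 0.405), and the difference among sets passed the F test (adjusted p = 0.00951). Against DHet, Fgfr4 was lower by log2 -0.70 in the set titled 8 day (adjusted p = 0.00212), with -0.05 (adjusted p = 0.95) in the 28-day set and -0.49 (adjusted p = 0.22) in the set titled 1 day. No other Fgfr4 probe set that passed the level filter was called in these comparisons. A probe outside the deleted part of a gene checks nothing about the deletion, and the position of these probes was not given in the sources used here.

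**Figure D1:**
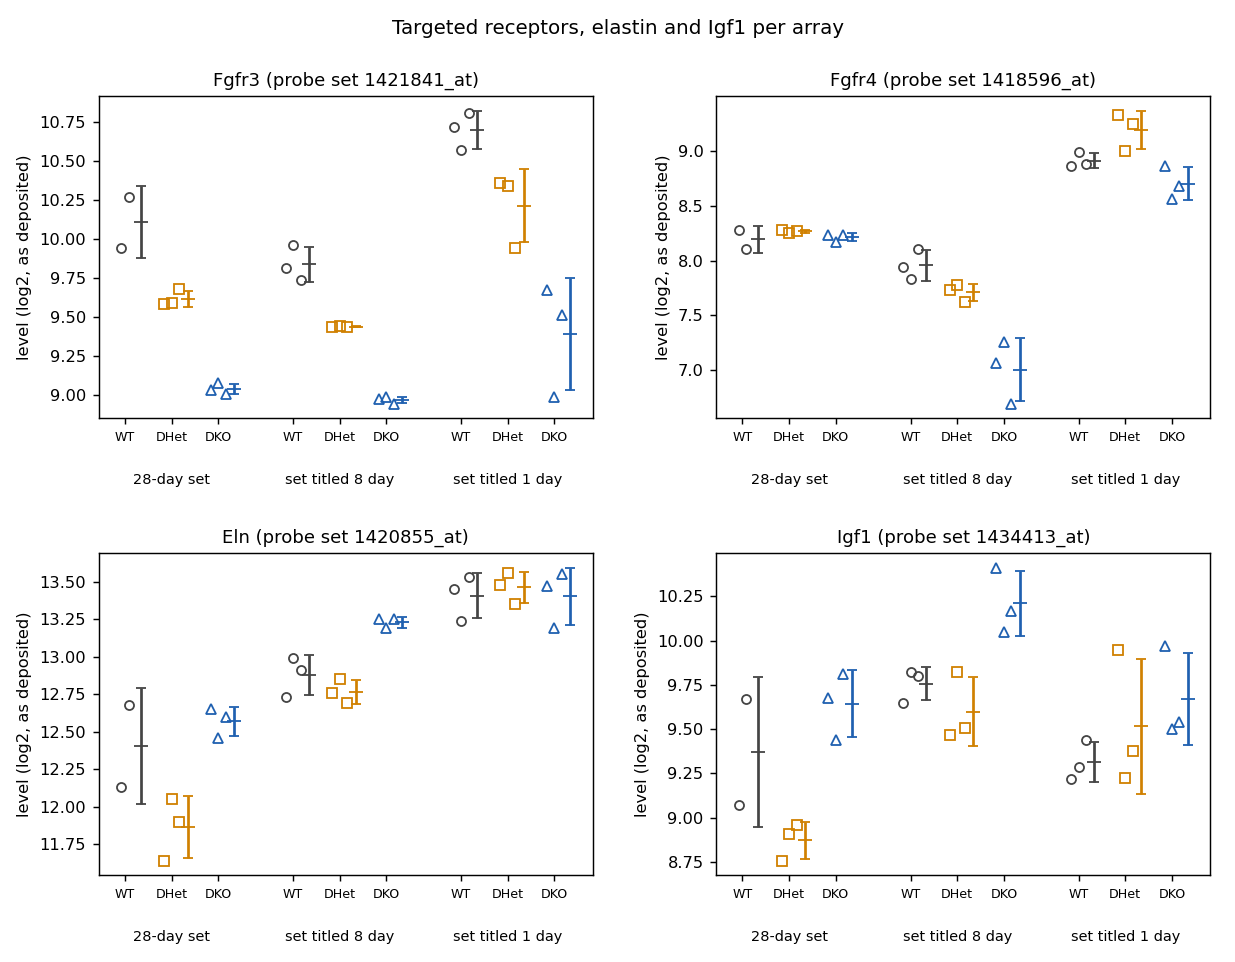
Level (log2, as deposited) of Fgfr3, Fgfr4, Eln and Igf1 on each array (open symbols) by genotype and set, with the group mean and SD beside the symbols; 1 probe set per gene. Fgfr3 lies lower in DKO than in WT in every set, while Fgfr4 does so past the test in the set titled 8 day, and levels are not comparable between sets, which look normalized separately.

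Eln, which encodes the elastin core of elastic fibres, and the growth factor gene Igf1 were compared as genes of alveolar growth. Neither differed past the test between DKO and WT within a set. Eln differed by log2 0.16 (adjusted p = 0.767), 0.36 (adjusted p = 0.131) and -0.01 (adjusted p = 0.991) in the 28-day set and the sets titled 8 day and 1 day. In that order Igf1 differed by 0.27 (adjusted p = 0.668), 0.45 (adjusted p = 0.156) and 0.35 (adjusted p = 0.342). Against DHet in the 28-day set both rose in DKO. Eln was 1.63-fold higher (12.57 ± 0.0981 SD against 11.86 ± 0.209 SD, n = 3 each, log2 0.70 ± 0.127 SE, adjusted p = 0.00216) and Igf1 1.71-fold higher (log2 0.77 ± 0.172 SE, adjusted p = 0.0122). The same differences were 0.46 (adjusted p = 0.073) and 0.61 (adjusted p = 0.0785) in the set titled 8 day, and -0.06 and 0.15 (adjusted p = 1 each) in the set titled 1 day. DHet differed from WT in Eln by -0.54 (adjusted p = 0.469), -0.10 (adjusted p = 0.94) and 0.06 (adjusted p = 0.835), and in Igf1 by -0.50 (adjusted p = 0.811), -0.16 (adjusted p = 0.924) and 0.20 (adjusted p = 0.524).

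The comparison of DKO with WT in the 28-day set asked what the loss of both receptors changed in lung some weeks after birth. The chitinase-like gene Chil4 was 5.59-fold higher (7.94 ± 0.941 SD, n = 3, against 5.46 ± 0.112 SD, n = 2, adjusted p = 2.53e-05). Its SD was larger in DKO, and the p rests on the spread shared over all groups. For Chil4 the p, here and against DHet, therefore does not measure the spread of the DKO arrays alone. Higher as well were the arginase gene Arg1 4.20-fold (adjusted p = 0.00809), Retnla 4.09-fold (adjusted p = 0.0116) and the acute phase gene Saa3 3.56-fold (adjusted p = 0.0157). Ankrd37, a hypoxia-inducible gene, was 4.04-fold higher and the Mediator kinase gene Cdk19 3.79-fold higher (log2 1.92 ± 0.151 SE, adjusted p = 2.23e-07). Igfbp3, which encodes a binding protein of insulin-like growth factors, was 5.26-fold lower (adjusted p = 0.0103), and 3.09-fold lower in its other probe set, which was not called (adjusted p = 0.0518). Lower too were Ankrd63 (3.85-fold), the lymphatic endothelial gene Lyve1 (3.45-fold, adjusted p = 0.000144), Ifi213 (3.29-fold), the dendritic cell lectin gene Cd209a (3.24-fold) and Gpr182, an endothelial receptor gene (3.14-fold, log2 -1.65 ± 0.131 SE, adjusted p = 2.23e-07).

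Among cell type lists in that comparison, lymphocyte markers fell, with 5 of 16 members lower over all genes and 12 adjusted over the list alone (median shift -0.49 log2, adjusted p = 1.35e-15, adjusted p = 0.000659 with an estimated correlation). Ccl5 was 2.93-fold lower, the cytotoxic granule gene Gzma 2.83-fold and the B cell receptor gene Cd79a 1.68-fold. Interferon response genes also fell, 3 of 19 over all genes and 9 adjusted over the list alone (shift -0.39, adjusted p = 1.09e-11, adjusted p = 0.00394 with an estimated correlation). Bst2 was 1.77-fold lower and Rtp4 1.65-fold lower. Endothelial markers fell as a list (4 lower and 2 higher of 24, adjusted over the list alone 10 and 2, shift -0.28, adjusted p = 6.27e-10, adjusted p = 0.0253 with an estimated correlation). Plvap, a gene of endothelial diaphragms, was 2.68-fold lower and Aplnr 2.68-fold lower, while Sox17 was 1.62-fold higher. Ciliated cell markers rose in 6 of 17 members (13 adjusted over the list alone, shift 0.39, adjusted p = 3.72e-12, adjusted p = 0.00171 with an estimated correlation), among them the dynein genes Dynlrb2 (log2 0.56) and Dnah9 (log2 0.42). Mesothelium markers rose as a list (1 of 11, 4 adjusted over the list alone, shift 0.25, adjusted p = 0.000366, adjusted p = 0.03 with an estimated correlation).

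Other lists passed only at the preset correlation. Macrophage markers rose in 4 of 22 members, 13 adjusted over the list alone (adjusted p = 4.72e-07, adjusted p = 0.101 with an estimated correlation). The scavenger receptor gene Marco was 3.22-fold higher and the mannose receptor gene Mrc1 1.49-fold. Smooth muscle and myofibroblast markers rose in 5 of 20, 9 adjusted over the list alone (adjusted p = 1.3e-06, adjusted p = 0.101 with an estimated correlation). Myl9 was 2.05-fold higher and Aspn, which lies within 20 Mb of Fgfr4, 3.12-fold. Collagens and other matrix genes rose in 4 of 24, 10 adjusted over the list alone (adjusted p = 8.63e-06, adjusted p = 0.101 with an estimated correlation). Col15a1 was 1.89-fold, Fn1 1.59-fold and Col1a1 1.54-fold higher, while another Col1a1 probe set did not share the sign. Matrix proteases and inhibitors rose in 3 of 18, with Ctsk log2 1.22 and Timp1 0.92 (adjusted p = 0.0135, adjusted p = 0.101 with an estimated correlation). Neutrophil and acute inflammation genes were not called as a list (1 of 16 higher, 2 adjusted over the list alone, shift -0.02, adjusted p = 0.37). In the hypoxia and glycolysis list 3 of 20 rose (adjusted p = 0.000535, adjusted p = 0.371 with an estimated correlation). In all, 511 probe sets were called, 285 higher and 226 lower in DKO, for 226 and 155 genes, and 3227 had an unadjusted p under 0.05. Without single arrays the count was 292 (DKO replicate 1), 308 (DKO replicate 3), 224 (WT replicate 1) and 164 (WT replicate 2). In simulated data 43.3% of differences of 0.5 log2 were called.

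DKO and WT lung of the set titled 8 day were compared in the same way. The glycoprotein gene Lrg1 was 5.52-fold higher (7.56 ± 1.18 SD against 5.09 ± 0.0921 SD, n = 3 each, adjusted p = 0.000206). As for Chil4, its SD was larger in DKO. Its p, here and against DHet, does not measure the spread of the DKO arrays alone. The acute phase gene Itih4 was higher 4.31-fold (adjusted p = 1.71e-05), the transcription factor gene Zbtb16 4.15-fold (adjusted p = 0.0418, with 1.83-fold and 1.19-fold in its 2 other probe sets, not called), Chil3 3.90-fold and the fatty acid binding protein gene Fabp4 3.74-fold. Cardiac myosin gene Myh6 was 3.76-fold higher (9.06 ± 0.193 SD against 7.15 ± 0.523 SD, n = 3 each, adjusted p = 8.67e-05). Wnt2, a signal of lung mesenchyme, showed the largest fall (3.37-fold lower, log2 -1.75 ± 0.204 SE, adjusted p = 2.67e-05). It was followed by the glycogen gene Ppp1r3c (2.81-fold), the protease gene Ctse (2.80-fold, another Ctse probe set did not share the sign), the protease inhibitor gene A2m (2.56-fold), Pisd-ps3 (2.48-fold) and the basement membrane gene Frem1 (2.37-fold, adjusted p = 0.00202).

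Heart muscle genes rose in 10 of 16 members in that comparison (14 adjusted over the list alone, shift 0.83 log2, adjusted p = 7.04e-19, adjusted p = 0.0235 with an estimated correlation). Tnnt2 was 3.20-fold and Tnni3 2.27-fold higher. The rise in heart genes moved with the groups, since Myh6 was 7.15 in WT, 8.08 in DHet and 9.06 in DKO. Macrophage markers rose in 13 of 22 members (17 adjusted over the list alone, shift 0.44, adjusted p = 5.42e-16, adjusted p = 0.00911 with an estimated correlation). Marco was 2.93-fold and Mrc1 1.51-fold higher. Ciliated cell markers rose in 11 of 17 (12 adjusted over the list alone, shift 0.48, adjusted p = 2.27e-13, adjusted p = 0.00219 with an estimated correlation). Dynlrb2 was 1.90-fold and Capsl 1.73-fold higher. Club cell markers rose in 7 of 17 (12 higher and 1 lower adjusted over the list alone, shift 0.59, adjusted p = 1.45e-11, adjusted p = 0.0235 with an estimated correlation). The haptoglobin gene Hp was 2.45-fold and the secretoglobin gene Scgb3a2 1.51-fold higher. Mesothelium markers rose in 5 of 11 (8 higher and 1 lower adjusted over the list alone, adjusted p = 6.55e-06, adjusted p = 0.00911 with an estimated correlation). Msln was 1.77-fold higher.

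Cell cycle genes lay lower as a list (1 of 28, 10 adjusted over the list alone, shift -0.40, adjusted p = 1.58e-10, adjusted p = 0.249 with an estimated correlation). Cenpa, which lies within 20 Mb of Fgfr3, was 1.59-fold lower. Lipofibroblast and matrix fibroblast markers held 5 lower and 2 higher of 18 (6 and 2 adjusted over the list alone, adjusted p = 0.0035, adjusted p = 0.217 with an estimated correlation), with Wnt2, Fgfr4 and Tcf21 (log2 -0.82) lower and Inmt (log2 1.86) higher. Glucocorticoid responsive genes held 5 higher and 1 lower of 18 (8 and 1 adjusted over the list alone, adjusted p = 7.27e-07, adjusted p = 0.265 with an estimated correlation). Lcn2 was at log2 1.89 and Mt1 at 0.92. Neutrophil and acute inflammation genes held 1 higher of 16, 3 adjusted over the list alone (shift 0.26, adjusted p = 0.00207, adjusted p = 0.366 with an estimated correlation). Alveolar type 2 markers held 3 higher of 19 (adjusted p = 0.000709, adjusted p = 0.249 with an estimated correlation). The surfactant genes Sftpa1 and Sftpd were higher by log2 0.37 and 0.44. Of the IGF system, which was not called as a list, Igfbp2 was 2.12-fold lower (adjusted p = 0.00138), Dlk1 2.47-fold higher (adjusted p = 0.00156) and Igf2 1.54-fold higher (adjusted p = 0.00576). The comparison called 1067 probe sets, 620 higher and 447 lower, for 467 and 346 genes. In simulated data 58.2% of differences of 0.5 log2 were called. The count was 516 without DKO replicate 2, 392 without DKO replicate 3, 449 without WT replicate 1 and 660 without WT replicate 3, and 336 with the spread of these groups alone. The signal ratio of 3' to 5' actin probe sets, a sign of RNA quality, was 0.50 ± 0.0994 log2 (SD) in DKO and 0.26 ± 0.115 in WT, n = 3 each.

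In the set titled 1 day 219 probe sets separated DKO from WT, against 511 in the 28-day set and 1067 in the set titled 8 day. After Fgfr3, A2m fell most (2.24-fold lower, 6.69 ± 0.4 SD against 7.86 ± 0.158 SD, n = 3 each, adjusted p = 0.000394). Next came the interferon-induced GTPase genes Gbp3 (1.79-fold, adjusted p = 0.0229) and Gbp6 (1.78-fold, adjusted p = 0.0498), the lymphatic growth factor gene Vegfd (1.74-fold, adjusted p = 0.0148) and the centromere gene Cenpa (1.70-fold, adjusted p = 0.00788). Sfxn1, which lies within 20 Mb of Fgfr4, was 2.02-fold higher (adjusted p = 0.0228), and 1.07-fold higher in its other probe set, which was not called (adjusted p = 0.641). Other rises were in Akap5 (1.99-fold), Adcy7 (1.95-fold), Ahnak2 (1.95-fold, adjusted p = 0.00993), Sema4f (1.94-fold) and Wdfy1 (1.89-fold, adjusted p = 0.0163). Alveolar type 1 markers rose in 3 of 15 members (11 adjusted over the list alone, shift 0.35, adjusted p = 2.46e-08, adjusted p = 0.106 with an estimated correlation). Hopx was 1.43-fold and Clic5 1.51-fold higher. Interferon response genes lay lower (1 of 19, 2 adjusted over the list alone, adjusted p = 1.55e-05, adjusted p = 0.106 with an estimated correlation), and lipofibroblast and matrix fibroblast markers too (2 of 18, adjusted p = 0.000631, adjusted p = 0.14 with an estimated correlation). Macrophage markers held 1 higher of 22, 7 adjusted over the list alone (adjusted p = 0.0043, adjusted p = 0.569 with an estimated correlation). Ciliated cell markers were not called (shift 0.03, adjusted p = 0.389). Of the 219, 175 were higher and 44 lower, and 3968 had an unadjusted p under 0.05. In simulated data 65.7% of differences of 0.5 log2 were called. The count was 37 without DKO replicate 1, 1280 without DKO replicate 2, 8 without WT replicate 1, 23 without WT replicate 2 and 450 without WT replicate 3. Limma called 0 probe sets, with 3106 at an unadjusted p under 0.05, when the spread came from these groups alone.

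**Figure D2:**
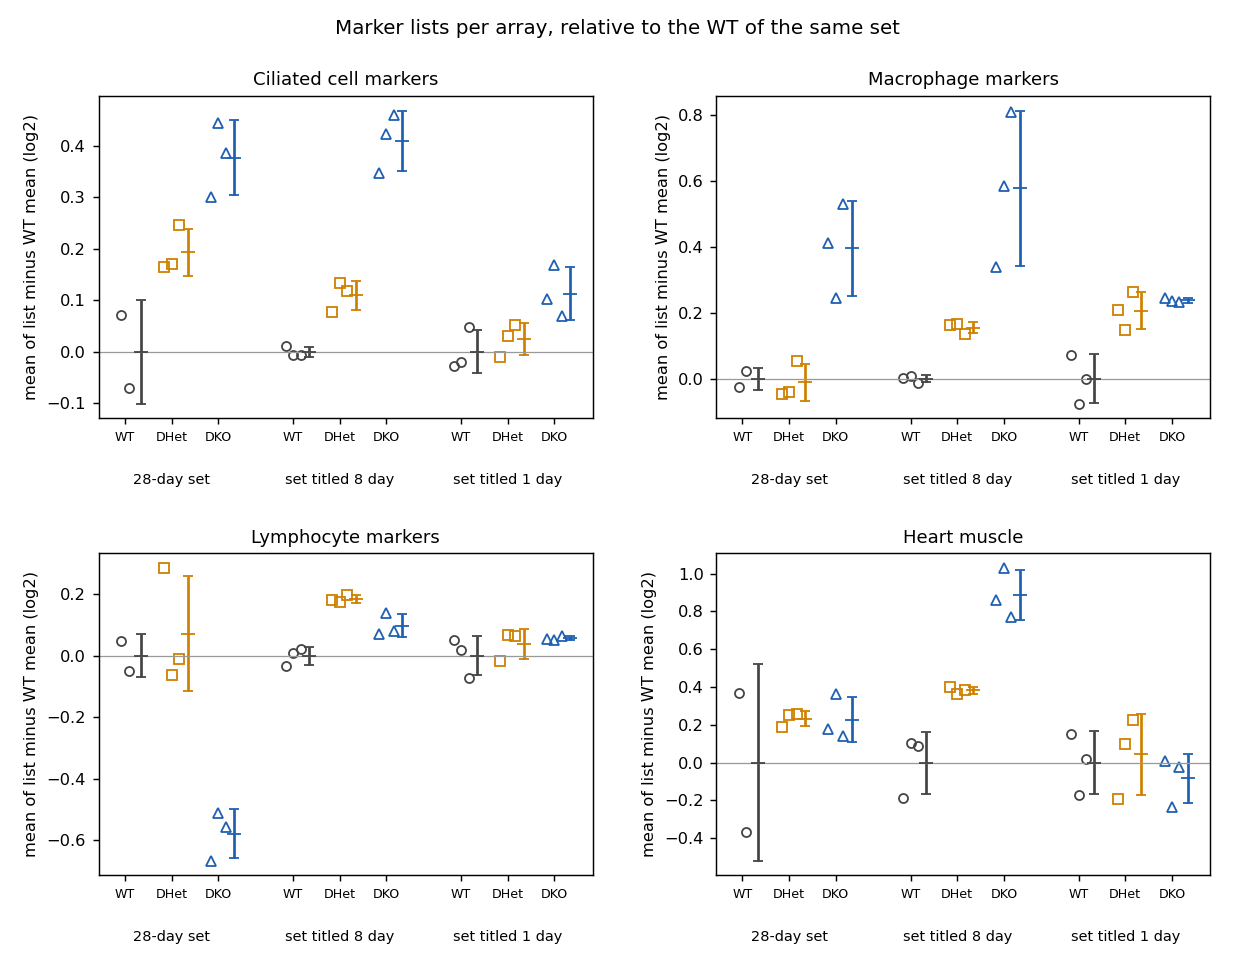
Mean log2 level of the measured members of 4 marker lists on each array, minus the WT mean of the same set (open symbols), with the group mean and SD beside the symbols. Ciliated cell and macrophage markers lie higher in DKO than in WT in the 28-day set and the set titled 8 day, lymphocyte markers lie lower in DKO of the 28-day set, and heart muscle genes lie higher in DKO of the set titled 8 day.

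Across the sets, which share no arrays, 68 genes were called higher in DKO than in WT in both the 28-day set and the set titled 8 day, where 5.67 would be shared by independent lists (Fisher's exact test, odds ratio 21.6, p = 1.01e-55). Among them were the ciliated cell genes Foxj1, Cfap126 and Dnah9 and the macrophage genes Marco and Mrc1. Another 11 were lower in both, where 1.42 would be shared, among them Fgfr3, Gpr182, Lyve1 and Hgf, which lies within 20 Mb of Fgfr3. The set titled 1 day shared 6 higher genes with the 28-day set (1.56 if independent) and 11 with the set titled 8 day (3.07 if independent). It shared 2 and 4 lower genes with them (0.146 and 0.191 if independent). Fisher's test takes genes as independent units, while genes of 1 cell type can move together. Its p therefore does not measure the variation between pools. The calls of different sets also rest on 1 spread per probe set shared by the fit. They are thus not fully independent, and the numbers for independent lists do not allow for that. By 1 probe set, the neurotrophin receptor gene Ntrk2, which lies within 20 Mb of Fgfr4, was 2.93-fold higher in the mean over the sets (adjusted p = 7.79e-05). In its 3 other probe sets the mean was 1.92-fold (adjusted p = 2.61e-06), 1.24-fold (adjusted p = 0.0174) and 1.14-fold (adjusted p = 0.105), and none of these 3 was higher in the set titled 1 day. Also higher in the mean were Marco (2.56-fold, adjusted p = 0.000117), Lrg1 (2.31-fold) and Ankrd37 (2.18-fold). Fgfr3 (log2 -1.08 ± 0.0789 SE, adjusted p = 4.31e-08), Lyve1 (1.98-fold lower), Mettl21e (1.94-fold lower) and A2m (1.85-fold lower, adjusted p = 2.2e-06) fell most. Igf1 rose by log2 0.36 ± 0.103 (adjusted p = 0.044), Fgfr4 fell by 0.38 ± 0.0687 (adjusted p = 0.00176) and Eln differed by 0.17 (adjusted p = 0.24). The set titled 8 day carries the fall in Fgfr4 (log2 -0.95, against 0.02 in the 28-day set and -0.21 in the set titled 1 day). Macrophage markers rose in 14 of 22 members (19 adjusted over the list alone, adjusted p = 4.45e-15, adjusted p = 0.00767 with an estimated correlation). Rises were also seen in ciliated cell markers, in 12 of 17 (14 adjusted over the list alone, adjusted p = 1.09e-14, adjusted p = 0.0012 with an estimated correlation), in club cell markers, in 8 of 17 (adjusted p = 9.01e-10, adjusted p = 0.0433 with an estimated correlation) and mesothelium markers in 7 of 11 (adjusted p = 2.28e-08, adjusted p = 0.00196 with an estimated correlation). Heart muscle genes, listed as a tissue that can be dissected along with lung, were higher in 6 of 16 (13 adjusted over the list alone, shift 0.31, adjusted p = 6.55e-08, adjusted p = 0.159 with an estimated correlation). Tnnt2 was 1.67-fold and Myh6 1.62-fold higher. Interferon response genes fell in 5 of 19 (adjusted p = 3.47e-10, adjusted p = 0.00763 with an estimated correlation) and lymphocyte markers in 3 of 16 (adjusted p = 7.65e-05, adjusted p = 0.0476 with an estimated correlation). The 28-day set carries the fall in lymphocyte markers, which were not called in the set titled 8 day (shift 0.07, adjusted p = 0.14) or the set titled 1 day (shift -0.06, adjusted p = 0.747). Interferon response genes were not called in the set titled 8 day (shift -0.03, adjusted p = 0.485), and heart muscle genes lay at -0.13 in the set titled 1 day (adjusted p = 0.0612). Club cell markers (shift 0.06, adjusted p = 0.237) and ciliated cell markers (shift 0.03, adjusted p = 0.389) were not called in the set titled 1 day. The mean called 1383 probe sets, 990 higher and 393 lower, and 858 without WT replicate 2 of the 28-day set.

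DKO was also compared with DHet, which asks what the loss of the remaining receptor copies changed. In the 28-day set Chil4 was 6.36-fold higher in DKO (7.94 ± 0.941 SD against 5.27 ± 0.0746 SD, n = 3 each, adjusted p = 9.44e-07). Ankrd37 was 4.89-fold higher, the pericyte gene Rgs5 4.51-fold (log2 2.17 ± 0.21 SE, adjusted p = 1.05e-06), Saa3 4.50-fold, Aspn 4.38-fold and Cdk19 4.32-fold (adjusted p = 6.51e-09). Igfbp3 was 4.80-fold lower (adjusted p = 0.00432), Ankrd63 4.56-fold, Lyve1 3.82-fold (adjusted p = 5.7e-06), Gzma 3.78-fold (adjusted p = 9.39e-05), Gpr182 3.16-fold and Ifi213 3.15-fold. Cell cycle genes rose in 12 of 28 members (20 adjusted over the list alone, shift 0.64, adjusted p = 6.77e-18, adjusted p = 0.0825 with an estimated correlation). Cdc20 was 2.02-fold and Cdk1 1.89-fold higher. Against WT of that set no member of this list was called in DKO (smallest adjusted p = 0.118, Cdc20), and the list lay lower in DHet than in WT. The rise is therefore one over DHet, and not shown over WT. Lymphocyte markers fell in 9 of 16 (12 adjusted over the list alone, shift -0.59, adjusted p = 9.84e-18, adjusted p = 0.00034 with an estimated correlation). Interferon response genes fell in 8 of 19 (12 adjusted over the list alone, adjusted p = 1.08e-13, adjusted p = 0.00263 with an estimated correlation). Endothelial markers fell in 10 of 24, with 2 higher (14 and 2 adjusted over the list alone, adjusted p = 1.29e-12, adjusted p = 0.0123 with an estimated correlation). Macrophage markers rose in 7 of 22 (13 adjusted over the list alone, adjusted p = 6.64e-11, adjusted p = 0.0285 with an estimated correlation), with the complement gene C1qc 1.64-fold higher, and collagens and other matrix genes in 7 of 24 (adjusted p = 4.16e-08, adjusted p = 0.0368 with an estimated correlation). Elastic fibre genes rose in 3 of 19, Eln, Mfap5 (log2 0.71) and Fbln2 (log2 0.66), with 5 adjusted over the list alone (adjusted p = 0.0229, adjusted p = 0.21 with an estimated correlation). The count was 819, with 390 higher and 429 lower. It was 444 without DHet replicate 1, 519 without DHet replicate 3, 398 without DKO replicate 1 and 450 without DKO replicate 3. In simulated data 67.2% of differences of 0.5 log2 were called. The Y-linked gene Eif2s3y was at 7.07 ± 0.556 SD in DKO and 4.46 ± 1.75 SD in DHet of this set (n = 3 each), a difference of log2 2.61 (adjusted p = 0.0838). A count of 312 probe sets was called with its level as a covariate.

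Against DHet, Lrg1 also led the rises in DKO of the set titled 8 day, 4.68-fold higher (7.56 ± 1.18 SD against 5.33 ± 0.24 SD, n = 3 each, adjusted p = 0.00116). Zbtb16 was 4.56-fold higher (adjusted p = 0.0492, with 1.80-fold and 1.275-fold in its 2 other probe sets, not called). Itih4 was 3.59-fold higher, Inmt 3.29-fold, the iron-binding lipocalin gene Lcn2 3.15-fold (adjusted p = 0.000786) and Fabp4 3.00-fold. Wnt2 was 3.14-fold lower (adjusted p = 0.000134), Ppp1r3c 2.50-fold, Lyve1 2.41-fold (adjusted p = 0.00236), Frem1 2.33-fold, A2m 2.28-fold and Fscn1 2.11-fold (adjusted p = 0.0128). Macrophage markers rose in 7 of 22 members (13 adjusted over the list alone, adjusted p = 8.49e-12, adjusted p = 0.0209 with an estimated correlation). Alveolar type 2 markers rose in 7 of 19 (11 adjusted over the list alone, adjusted p = 1.33e-09, adjusted p = 0.0287 with an estimated correlation). Ciliated cell markers rose in 6 of 17 (9 adjusted over the list alone, adjusted p = 0.00706 with an estimated correlation) and mesothelium markers in 5 of 11 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00546 with an estimated correlation). The surfactant genes Sftpa1 and Sftpd were higher by log2 0.49 and 0.58. Heart muscle genes rose in 4 of 16 (8 adjusted over the list alone, adjusted p = 6.17e-10, adjusted p = 0.135 with an estimated correlation). The count was 436, with 332 higher and 104 lower. In simulated data 61.2% of differences of 0.5 log2 were called. The count was 205, 246 and 231 without DHet replicate 1, 2 and 3, 223 without DKO replicate 2 and 145 without DKO replicate 3, and 136 with the spread of these groups alone. Actin 3' to 5' ratios were 0.50 log2 in DKO and 0.35 in DHet.

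A count of 7 probe sets of the set titled 1 day separated DKO from DHet. The ciliary gene Lrrc23 was 1.57-fold higher in DKO (log2 0.65 ± 0.115 SE, n = 3 each, adjusted p = 0.0479). In turn Clmp (1.78-fold), Fgfr3 (1.77-fold), the ceruloplasmin gene Cp (1.73-fold), all with adjusted p = 0.0232, the calcium channel gene Cacna1d (1.56-fold, adjusted p = 0.0258) and Mxra8 (1.31-fold, adjusted p = 0.0446) were lower. None of the other Cp probe sets was called, and the one with the highest level was 1.305-fold lower (adjusted p = 0.717). The other probe sets of Clmp (1.80-fold lower, adjusted p = 0.057) and Cacna1d (1.195-fold lower, adjusted p = 0.871) were not called. Lipofibroblast and matrix fibroblast markers fell as a list, with no member of 18 called over all genes and 7 lower adjusted over the list alone (shift -0.30, adjusted p = 1.66e-11, adjusted p = 0.00607 with an estimated correlation). The list holds Fgfr4, a targeted gene (log2 -0.49, adjusted p = 0.22). At an unadjusted p under 0.05 there were 1201 probe sets. In simulated data 56.7% of differences of 0.5 log2 were called. Without single arrays the count was 1 (DHet replicate 1), 22 (DHet replicate 2), 21 (DKO replicate 1) and 4 (DKO replicate 3), and with the spread of these groups alone limma called 0, with 362 at an unadjusted p under 0.05.

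Averaged over the sets, Ankrd37 (2.63-fold), Ntrk2 (2.27-fold, adjusted p = 1.2e-07), the endothelin gene Edn1 (2.27-fold, adjusted p = 0.00244), which like Ntrk2 lies within 20 Mb of Fgfr4, and Cdk19 (2.16-fold) were higher in DKO than in DHet. Cyp1a1 (2.91-fold, adjusted p = 0.0453), Lyve1 (2.24-fold), Wnt2 (1.90-fold) and Gpr182 (1.71-fold, adjusted p = 7.7e-07) were lower. Fgfr3 fell by 0.62 ± 0.0758 log2 (adjusted p = 4.99e-05) and Fgfr4 by 0.42 (adjusted p = 0.000746), while Eln rose by 0.37 ± 0.0733 (adjusted p = 0.00541) and Igf1 by 0.51 ± 0.0991 (adjusted p = 0.00431). Within sets Eln and Igf1 passed the test only at 28 days, and Eln had the opposite sign in the set titled 1 day. Fgfr4 passed it within sets only in the set titled 8 day. Macrophage markers rose in 11 of 22 members (adjusted p = 2.62e-14, adjusted p = 0.0096 with an estimated correlation). Ciliated cell markers rose in 9 of 17 with 1 lower (adjusted p = 8.08e-11, adjusted p = 0.00317 with an estimated correlation) and mesothelium markers in 5 of 11 (adjusted p = 0.00317 with an estimated correlation). Endothelial markers fell in 8 of 24 with 1 higher (adjusted p = 8.91e-09, adjusted p = 0.0307 with an estimated correlation). Lymphocyte markers fell in 6 of 16 (adjusted p = 1.55e-08, adjusted p = 0.00715 with an estimated correlation) and interferon response genes in 3 of 19 (adjusted p = 7.05e-06, adjusted p = 0.0448 with an estimated correlation). The 28-day set carries both of the latter, since lymphocyte markers shifted by -0.03 (adjusted p = 0.0729) and 0.06 (adjusted p = 0.42), and interferon response genes by -0.02 (adjusted p = 0.402) and 0.01 (adjusted p = 0.915), in the sets titled 8 day and 1 day. Endothelial markers were not called in the set titled 8 day (shift -0.01, adjusted p = 0.433). In the set titled 1 day macrophage markers (shift 0.04, adjusted p = 0.173) and mesothelium markers (shift 0.05, adjusted p = 0.32) were not called. The mean called 920 probe sets, 491 higher and 429 lower.

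DHet was compared with WT to ask what the heterozygous mutations changed. In the 28-day set Wdfy1 was 2.27-fold higher in DHet (7.15 ± 0.135 SD, n = 3, against 5.96 ± 0.326 SD, n = 2, adjusted p = 0.0304) and Abhd1, which lies within 20 Mb of Fgfr3, 1.69-fold higher (adjusted p = 0.0126). Npas2, a clock gene, was 3.07-fold lower (adjusted p = 0.0487), and 1.34-fold lower in its other probe set, which was not called (adjusted p = 0.584). Lower as well were Cd209a 2.42-fold (adjusted p = 0.000421), Sptlc1, which lies within 20 Mb of Fgfr4, 1.89-fold, with 2 other probe sets of the opposite sign, and the macrophage lectin gene Mgl2 1.71-fold. These were the 6 probe sets called, with 1489 at an unadjusted p under 0.05. The count was 1 without DHet replicate 2 or replicate 3 and 12 without WT replicate 1, and limma called 0 (1827 at an unadjusted p under 0.05) with the spread of these groups alone. In simulated data 29.9% of differences of 0.5 log2 were called. Of the lists 9 were called at the preset correlation, 7 higher and 2 lower in DHet, and 0 with an estimated correlation. The higher ones are not described here. Cell cycle genes lay lower as a list (no member of 28 called over all genes, 7 adjusted over the list alone, shift -0.43, adjusted p = 3.82e-16, adjusted p = 0.276 with an estimated correlation).

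In the set titled 8 day Ctse was 3.70-fold lower in DHet than in WT (5.66 ± 0.0752 SD against 7.55 ± 0.0999 SD, n = 3 each, adjusted p = 3.42e-07), with another Ctse probe set of the opposite sign. The mitochondrial transhydrogenase gene Nnt was 2.37-fold lower (adjusted p = 0.000283), the complement inhibitor gene Cd59a 1.99-fold (adjusted p = 1.72e-05) and Cdk5rap1 1.77-fold (adjusted p = 0.0278). The autophagy gene Atg7 was 1.37-fold higher (adjusted p = 0.00653), although its 2 other probe sets did not share the sign. Lists called at the preset correlation numbered 8, with 6 higher and 2 lower in DHet, and 0 with an estimated correlation. Among them heart muscle genes lay higher, with no member of 16 called over all genes and 7 adjusted over the list alone (shift 0.37, adjusted p = 5.11e-11, adjusted p = 0.161 with an estimated correlation). The count was 14, with 2023 at an unadjusted p under 0.05 and 23 without WT replicate 2. In simulated data 64.2% of differences of 0.5 log2 were called.

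DHet of the set titled 1 day differed from WT at 1373 probe sets, 1203 of them higher. The nuclear RNA Neat1 was 2.75-fold higher (11.61 ± 0.875 SD against 10.15 ± 0.296 SD, n = 3 each, adjusted p = 0.0245, another Neat1 probe set did not share the sign). The matrix gene Thbs3 was 2.68-fold higher (adjusted p = 0.00721), Misp3 2.55-fold (adjusted p = 0.00131) and the ciliated cell gene Tppp3 2.39-fold (adjusted p = 0.00105). A2m was 2.27-fold lower (adjusted p = 0.00024), the lipid desaturase gene Scd1 2.22-fold (adjusted p = 0.0362), the glucocorticoid-induced factor gene Klf9 2.01-fold and Cap1 1.96-fold. None of the other Klf9 probe sets was called, and the one with the highest level was 1.35-fold lower (adjusted p = 0.286). The other Scd1 probe set was 1.75-fold lower and not called (adjusted p = 0.0506). At the preset correlation 9 lists were called, 4 higher and 5 lower in DHet, and 0 with an estimated correlation. The lower ones are not described here. Alveolar type 1 markers rose in 10 of 15 members (13 adjusted over the list alone, shift 0.47, adjusted p = 1.73e-08, adjusted p = 0.234 with an estimated correlation). Clic5 was at log2 0.79, Hopx at 0.61 and Akap5 at 1.14. Endothelial markers rose in 5 of 24 (10 adjusted over the list alone, adjusted p = 0.0201, adjusted p = 0.582 with an estimated correlation), with Vwf at log2 0.59 and Car4 at 0.89, and alveolar type 2 markers in 5 of 19 (adjusted p = 0.017, adjusted p = 0.582 with an estimated correlation). DHet replicate 1 lay lowest on the first principal component of its set (-41.0, with the others between -23.5 and 22.6), and DKO replicate 1 was next. Deviations from the group means correlated at r = 0.548 between these arrays and at 0.566 between DHet replicate 2 and DKO replicate 3. Over pairs of arrays of unlike genotype in this set r ran from -0.521 to 0.566, so arrays also grouped across genotypes. Xist was at 8.09 ± 3.47 SD in DHet against 10.8 in WT (n = 3 each). The count was 318 without DHet replicate 1, 182 without WT replicate 1, 284 without WT replicate 2 and 821 with Eif2s3y as a covariate. Limma called 0, with 4462 at an unadjusted p under 0.05, when the spread came from these groups alone. In simulated data 58.2% of differences of 0.5 log2 were called.

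The list of FGF ligands, receptors and targets, which holds the genes nearest to the mutated receptors, was not called in any comparison of genotypes within a set. Its 18 measured members had adjusted p = 0.892, 0.851 and 0.972 in DKO against WT in the 28-day set and the sets titled 8 day and 1 day. The feedback gene Dusp6 was 1.48-fold higher in DKO than in WT of the 28-day set with an adjusted p of 0.0502, and higher by log2 0.59 than in DHet (adjusted p = 0.0136). Fgf1 was 1.52-fold higher in DKO than in WT of the set titled 1 day (adjusted p = 0.0144). The IGF system was not called either, although Pappa2, which cleaves IGF binding proteins, was 2.49-fold higher in DKO than in WT of the 28-day set (adjusted p = 0.00249) and 2.69-fold higher than in DHet (adjusted p = 0.000186).

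The WT of the 3 sets were compared to describe lung at different ages, as far as sets that look normalized separately allow. Between the 28-day set and the set titled 8 day the median of all probe sets differed by 0.45 log2. Relative to it, Ms4a4d (6.17), the methyltransferase gene Inmt (5.02) and the cytochrome genes Cyp2b10 (4.76) and Cyp1a1 (4.64) were higher at 28 days. Conversely Prss35 (-5.22), the matrix genes Tnc (-4.56) and Fbn2 (-4.26) and the protease inhibitor gene Stfa2l1 (-4.49) were lower. Cell cycle genes were lower at 28 days relative to the median in 28 of 28 members (shift -1.70, adjusted p = 1.79e-23, adjusted p = 0.121 with an estimated correlation). Club cell markers were higher relative to it in 15 of 17 (shift 1.31, adjusted p = 0.00228, adjusted p = 0.295 with an estimated correlation). Against the set titled 1 day, with a median difference of -0.69, the antigen presentation gene H2-Aa (5.27), the retinol acyltransferase gene Lrat (5.21), Chil3 (5.04) and Cyp2b10 (4.92) were higher at 28 days relative to the median. The imprinted gene Dlk1 (-8.21), Stfa2l1 (-6.71), Stfa3 (-5.56) and Col25a1 (-5.14, against -0.60 in its other probe set) were lower. Lymphocyte markers were higher relative to all genes (13 of 16 above the median difference, shift 1.503, adjusted p = 3.44e-10, adjusted p = 0.00738 with an estimated correlation), as were endothelial markers (23 of 24, shift 0.73, adjusted p = 3.44e-10, adjusted p = 0.0405 with an estimated correlation).

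Between the set titled 8 day and the set titled 1 day the median difference was -1.13 log2. Relative to it Nav2 (3.87, with 3 of 6 other probe sets of the same sign on this scale), Wnt5a (3.68), H2-Aa (3.62) and Prss35 (3.51) were higher in the set titled 8 day. There Dlk1 (-5.04), Fabp4 (-4.99, against -1.935 in its other probe set), Zbtb16 (-4.40, against -4.105 and -1.03 in its 2 others) and Nfe2l2 (-4.36, against 0.45 in its other probe set) were lower. Cell cycle genes were higher relative to all genes (shift 1.39, adjusted p = 2e-39, adjusted p = 0.0288 with an estimated correlation), and so were smooth muscle and myofibroblast markers (shift 0.95, adjusted p = 8.55e-14, adjusted p = 0.0288 with an estimated correlation) and elastic fibre genes (shift 0.67, adjusted p = 3.75e-05, adjusted p = 0.0288 with an estimated correlation). For the IGF system the median shift was -0.14 while the test pointed up (adjusted p = 0.0295, adjusted p = 0.0589 with an estimated correlation). As deposited, the comparisons called 19510, 22062 and 25115 probe sets, with 16785, 1834 and 578 of them higher in the set named first. After quantile normalization the counts were 15977, 16232 and 18039, with 7456, 7564 and 9243 higher. The split in direction therefore depends on the normalization. Lists in the comparisons between sets were not tested again after quantile normalization, so whether their shifts depend on it was not tested. Relative to the median, Eln of the elastic fibre list was 0.60 log2 higher in WT of the set titled 8 day. After quantile normalization Eln differed there by 0.09 ± 0.132 (SE), while cell cycle genes were higher in 28 of 28 members.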

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

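Of the tests in this part, strain as the whole cause, sex as the whole cause and the tests on DHet against WT in the set titled 1 day were chosen after the result was seen.

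The difference between DKO and WT was not the same in the 3 sets for 324 probe sets, by the moderated F test. Cd209a had the smallest adjusted p (0.00036), with log2 -1.70 in the 28-day set, -0.01 in the set titled 8 day and -0.04 in the set titled 1 day. In the same order, the endothelial gene Gpr182 differed by -1.65, -0.54 and -0.09 (adjusted p = 0.000541), Hp by 0.39, 1.29 and 0.12 (adjusted p = 0.000753) and Cdk19 by 1.92, 1.07 and 0.21 (adjusted p = 0.000882). Cd59a differed by -0.09, -0.96 and 0.09, Ankrd63 by -1.94, 0.15 and -0.12 and Ntrk2, which lies within 20 Mb of Fgfr4, by 1.74, 1.12 and -0.05 (adjusted p = 0.00186 each). The integrin gene Itga6 differed by -0.90, -0.41 and 0.05 (adjusted p = 0.00189). Fgfr4 differed by 0.02, -0.95 and -0.21 (adjusted p = 0.00951). The F count was 200 without DKO replicate 1 of the 28-day set, 194 and 182 without WT replicate 1 and 2 of that set, 165 and 197 without DKO replicate 2 and 3 of the set titled 8 day and 209 without its WT replicate 1. It was 214 and 945 without DKO replicate 1 and 2 of the set titled 1 day and 149 and 191 without its WT replicate 1 and 2. Among 100 splits of the arrays within sets, 2 gave as many, the real split and 1 other, which gave 839, well above the real count. The share is under 0.05, but that split points to a structure of the arrays other than genotype.

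For the first pattern, the genes that differ between DKO and WT, a strain background that DKO and DHet share in equal measure is argued against as the whole cause. The test cannot speak to a background that they carry in unequal amounts. The background of the mutants was not given in the sources used here. Calls of DKO against WT in 1 set and DKO against DHet in another were shared 9.03 times as often as independent lists would share (164 against 18.2). That ratio takes genes as independent units, although genes of 1 cell type can move together. It also takes calls of different sets as independent, although the fit shares 1 spread per probe set between them. Sex as the whole cause is argued against too, as 70.8% or more of the calls in each set were still called with Eif2s3y as a covariate. Flanking DNA from another strain may explain some calls, as 41 of 808 called genes lay within 20 Mb of either locus (odds ratio 1.67, 95% interval 1.17 to 2.34, Fisher's exact test, p = 0.00371), and the odds ratio was 1.78 (p = 0.00553) in the set titled 8 day, but 1.43 (p = 0.192) and 1.59 (p = 0.287) in the 28-day set and the set titled 1 day and 1.05 (p = 0.802) for the mean of DKO against DHet, where flanking DNA would differ too. Heart tissue may explain the cardiac genes of the set titled 8 day, where the heart list shifted by 0.83 log2. The mean level of its members, relative to all genes, differed by 0.87 ± 0.12 log2 (SE over arrays). Myl7 was at 8.47 in WT and 9.92 in DKO, and Actc1 at 8.91 and 9.69. Whether these transcripts came from dissected heart or from the lung itself was not tested. Open remain a strain background that differs between DKO and DHet, and part of the calls through one that they share. For the latter, calls were shared with DHet against WT of another set 1.77 times as often as by independent lists, 66.3% in the same direction. Open too are other tissue in the other 2 sets (adipose 0.17 in the 28-day set, cartilage -0.14 in the set titled 1 day), sex (Eif2s3y 0.58 ± 0.637 in the set titled 8 day) and the loss of the receptors itself.

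The second pattern is the conflict of ages in the labels of 18 samples. If the titles gave the age, Eln was to be higher in the set titled 8 day in all 3 genotypes, and after quantile normalization it differed by 0.09 in WT, -0.0102 in DHet and 0.44 in DKO (SE 0.132 each). Relative to the median of all probe sets it was higher in all 3 (0.60, 0.48 and 0.97), and as deposited lower in all 3 (-0.53, -0.70 and -0.17). Cell cycle genes, which were to differ, were higher in the set titled 8 day in 28 of 28 members in each genotype after quantile normalization, but a difference in either direction would have met that. Since the answer for Eln depends on the scaling and the sets look normalized separately, these tests cannot tell the labels apart. Other genes that differ between the sets were not tested against the labels.

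The third pattern is the 1373 probe sets called between DHet and WT in the set titled 1 day. The shared spread may explain this count, since limma called 0 with the spread of the 2 groups alone (4462 at an unadjusted p under 0.05), which also rests on fewer degrees of freedom. A single array stays open as the source, with 318 called without DHet replicate 1, because 182 were called without WT replicate 1 and 284 without WT replicate 2. The heterozygous mutations stay open as well. The labels give both groups the same age, and whether the animals differed in age was not tested.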

How the results depend on the processing

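The alternatives with Eif2s3y as a covariate and with array medians subtracted were chosen after the data were seen.

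Array weights changed 10 counts by more than 1.5 times: DKO against WT gave 1084, 1746 and 1898 in the 28-day set and the sets titled 8 day and 1 day, DKO against DHet 2326, 1476 and 3, and DHet against WT 2692 in the set titled 1 day. The means over sets gave 2328 for DKO against WT and 1548 for DKO against DHet, and the F test 1666. The replicate number as a block gave 273 for DKO against WT in the 28-day set and 109 in the set titled 1 day, 1 for DKO against DHet in the set titled 1 day, 1 for DHet against WT in the 28-day set and 156 for the F test. Replicate numbers did not pair the arrays, since residuals of arrays with the same number correlated above 0.1 in 2 of 7 pairs of the 28-day set, 0 of 9 of the set titled 8 day and 3 of 9 of the set titled 1 day. The fit on the groups compared alone gave 336 and 0 for DKO against WT in the sets titled 8 day and 1 day, 136 and 0 for DKO against DHet there, and 0 for DHet against WT in the 28-day set and the set titled 1 day. Where limma called 0 in this fit, unadjusted p values under 0.05 numbered 3106 and 362 for DKO against WT and DHet in the set titled 1 day, and 1827 and 4462 for DHet against WT in the order given. The covariate Eif2s3y gave 312 and 1 for DKO against DHet in the 28-day set and the set titled 1 day, and 1 and 821 for DHet against WT in the same sets. For these 4 alternatives the cause was not tested.

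DKO against WT of the set titled 1 day gave 448 with the offset and 410 after quantile normalization, which called 281 higher and 129 lower. DKO against DHet of that set gave 14 with the offset, 15 after quantile normalization and 11 with trend and robust options. The cause was not tested. The upper 40% of probe sets gave 334 for DKO against WT and 12 for DKO against DHet in the set titled 1 day and 2 for DHet against WT in the 28-day set, where the cause was not tested. For the comparisons of WT between sets it gave 12795 (28-day set and titled 8 day), 14157 (28-day set and titled 1 day) and 16443 (titled 8 day and titled 1 day), as fewer probe sets were tested, and no filter gave 38696 and 42341 for the latter 2, as more were tested. A fold of at least 1.5 left 284, 352 and 77 for DKO against WT, 405 and 199 for DKO against DHet in the 28-day set and the set titled 8 day, 306 for DHet against WT in the set titled 1 day, 97 and 71 for the means and 12120 for WT of the 28-day set and the set titled 8 day, since it keeps fewer probe sets. With array medians subtracted the WT counts were 16769, 16851 and 19546. Other counts stayed within 1.5 times under the alternatives run.

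Leaving out 1 array gave 164 to 421, 392 to 1055 and 8 to 1280 for DKO against WT, 398 to 741, 145 to 575 and 1 to 22 for DKO against DHet, and 1 to 12, 11 to 23 and 182 to 1813 for DHet against WT, in the order 28-day, titled 8 day, titled 1 day. The means over sets gave 858 to 1769 and 676 to 1007, the F test 149 to 945, and the comparisons of WT 17291 to 18888, 20327 to 21620 and 24708 to 24969. Without a WT array of the 28-day set the lone WT array is assumed to vary like the other groups. Lower counts go with fewer arrays, and the cause of higher ones was not tested. For Fgfr4, 2 probe sets lay below the level filter, where low signal limits what can be read, and their values are not given here.

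Of 95 calls of lists in the comparisons within sets, 24 passed with an estimated correlation, and 94 to 98 lists were called under the other alternatives. The hypoxia and glycolysis list in DKO against DHet of the set titled 1 day, which was called, reversed to -0.04461 with array weights. Of 158 calls of named genes 127 to 155 passed under the alternatives and 134 to 152 without 1 array. Of the 149 that do not come from the F test, 104 were still called whichever array was left out and 45 were lost without at least 1 array.

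Other reversals were of uncalled differences, the largest of them Igf1 (0.27) and Eln (0.16) in DKO against WT of the 28-day set and Igf1 (0.20) in DHet against WT of the set titled 1 day. Without 1 array, DKO against WT in the 28-day set ran from -0.0679 to 0.11 for Fgfr4, -0.0669 to 0.0426 for probe set B of its other kept probe sets A and B, -0.12 to 0.44 for Eln and -0.0263 to 0.57 for Igf1. Probe set B of Fgfr4 ran from -0.0527 to 0.0178 in the set titled 8 day, and Eln from -0.0888 to 0.0992 in the set titled 1 day. For DKO against DHet, Eln ran from -0.13 to 0.0426 in the set titled 1 day and probe set B of Fgfr4 from -0.0237 to 0.0205 in the mean. For DHet against WT in the 28-day set, the second Fgfr3 probe set ran from -0.15 to 0.0103 and Fgfr4 from -0.0159 to 0.16. For the set titled 8 day, probe sets A and B of Fgfr4 ran from -0.0309 to 0.0449 and -0.00849 to 0.062. For the set titled 1 day, probe set B of Fgfr4 ran from -0.0156 to 0.045, Eln from -0.0266 to 0.12 and Igf1 from -0.0145 to 0.35. Array weights gave Eln 0.0754 and 0.0624 in DKO against WT and DHet of the set titled 1 day, and probe set B of Fgfr4 -0.0138 in DHet against WT there and 0.0158 in the mean of DKO against DHet. Quantile normalization gave -0.0242 for probe set B of Fgfr4 and -0.0162 for Eln in DHet against WT of the set titled 1 day. The block gave 0.0108 for probe set B of Fgfr4 in DKO against WT of the 28-day set. With Eif2s3y as a covariate, Fgfr4 gave 0.0264 in DKO against DHet of the 28-day set and probe set B of Fgfr4 0.00176 in the mean. The cause was not tested.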

Other observations

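The levels of Abhd1, Nnt and Cd59a given here were chosen after their values were seen, and the tests of other splits were planned.

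Abhd1, which lies within 20 Mb of Fgfr3, was called higher in DKO than in WT in all 3 sets, by log2 1.15 (adjusted p = 4.83e-06), 0.95 (adjusted p = 1.31e-05) and 0.64 (adjusted p = 0.00666) in the 28-day set, the set titled 8 day and the set titled 1 day. Its mean level in WT, DHet and DKO had the same order in each set (5.83, 6.59 and 6.97; 5.47, 5.94 and 6.42; 6.65, 7.04 and 7.29). Nnt was at 9.10 in WT, 7.85 in DHet and 8.75 in DKO of the set titled 8 day. In the same order it was at 8.13, 8.77 and 8.87 in the set titled 1 day and at 8.02, 8.21 and 8.61 in the 28-day set. DHet thus lay below WT in the set titled 8 day and above it in the other sets. Whether the WT of the sets differ in background was not tested. Cd59a was at 8.53 in WT and at 7.54 and 7.58 in DHet and DKO of the set titled 8 day.

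Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split is among them and is counted in the numbers of splits as large. The real split gave 1067 probe sets for DKO against WT in the set titled 8 day (1 of 10 splits as large, highest other 22) and 219 in the set titled 1 day (2 of 10, highest other 809). DKO against DHet gave 819 in the 28-day set (1 of 10, highest other 4), 436 in the set titled 8 day (1 of 10, highest other 0) and 7 in the set titled 1 day (7 of 10, highest other 1121). DHet against WT gave 14 in the set titled 8 day (1 of 10, highest other 5) and 1373 in the set titled 1 day (1 of 10, highest other 9). WT of the sets titled 8 day and 1 day gave 25115 (1 of 10, highest other 0). In the set titled 1 day, splits that called several times the real count point to a structure of the arrays other than genotype. For the means over sets 1 of 100 splits was as large for DKO against WT (1383, highest other 652) and 1 of 100 for DKO against DHet (920, highest other 157), in both the real split itself. Chance is therefore excluded at a share of 0.05 for both.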
